A study of Homo sapiens with 6 samples.

How the data were processed

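The series holds 6 RNA-seq libraries of CAMA1 cells, 3 given vehicle (PBS) and 3 given FGF2 at 5 ng/ml for 6 h after 24 h without serum. Per the labels' protocols, RNA was purified from cells in dishes, passed a check of its integrity, and went through poly(A) selection, fragmentation and a strand-specific library kit before sequencing on an Illumina instrument. The deposited table holds expected counts, that is counts per gene that need not be whole, for 26485 gene symbols with the exon coordinates of their models. Per the submitters' processing notes the genome build was hg38 and the tools were STAR, Subread and featureCounts, with no version or setting. The annotation's version, the strand setting and the handling of reads that match several places are not given in the sources used here. Of all values 86.5% were whole within 0.001, and of the values above 0 80.9% were, so part of the reads were divided between genes or positions. Whether genes on opposite strands were told apart is not known. Genes whose exons overlap another gene, or which hold fractional counts, are therefore named in a paragraph that gives their values, which are uncertain for that reason. The table's columns and the labels name FGF2, while the name given to the table itself names another FGF ligand, and the groups follow the labels.

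Counts were rounded to whole numbers. Models on more than 1 chromosome or contig were listed for 1205 genes, and positions are printed for the reference chromosome. Gene types came from the RefSeq gene table of GRCh38.p14 by current symbol for 23758 genes and by synonym for 1562, and 1165 had no match. No gene of the mitochondrial chromosome was in the table. Of the genes, 5228 had 0 counts in all libraries. Totals per library were 21609117, 22707039 and 23598392 for vehicle replicates 1 to 3 and 23035030, 22358660 and 22676975 for FGF2 replicates 1 to 3. All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 4.59 to 38.5), so no library was counted as a copy of another. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 1 to 3 counts over the vehicle group has its ratio with an exact 95% counting interval, and a gene with 0 has a lower bound against a floor of 3 counts over the group.

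The test was edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM factors, robust dispersion and the quasi-likelihood F test on group alone, two-sided, with Benjamini-Hochberg adjustment over 14570 genes and a threshold of 0.05. The fit left 4 residual degrees of freedom and a common biological coefficient of variation of 5.54%. Standard errors are the log2 fold change divided by the root of F. Of 27 gene lists, the 24 with at least 5 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, which asks whether a list's genes move on balance in one direction without setting them against other genes, were alternatives. Members of each list were also counted when adjusted over the list alone. Some genes stand on more than 1 list. The lists cover FGF and MAPK signalling, early genes, estrogen receptor, luminal and basal genes, cell cycle, growth, metabolism, stress, inflammation, apoptosis, histones, ribosomal proteins, the 8p11-p12 region and markers of other cell types. Lists, tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as added later. The named genes were the 12 risen and the 12 fallen protein-coding genes with the largest change among those past the threshold, with a mean of at least 5 CPM and all libraries of one group above all of the other. They also held up to 4 genes with the largest change past the threshold from each list, or up to 2 with the smallest p where none passed, and a set that included the FGF receptors, FGF2, ESR1, PGR, GREB1, CCND1, MYC, SPRY4, DUSP6, ETV4 and ETV5. The text gives examples from these 125 genes, and some of them are not reported here.

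The procedure was tested on simulated counts drawn from the means and library sizes of this comparison for 14392 genes. Of 50 genes changed at each fold it recovered 50% at 1.2-fold, 84% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 13 false calls among 178, and called none of 24 unchanged lists at the adjusted threshold. The simulated genes varied independently, so the list result does not cover false calls from correlated genes. In the data 60.4% of the tested genes changed, far more than in the simulation, so the recovery shares need not hold there. The alternatives were other scalings (DESeq2's size factors, upper quartile), no filter on low counts and a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), DESeq2 1.42.0, limma voom, the fit without robust shrinkage, the replicate number as a block, each library left out in turn, and a test against a fold of 1.5. Added after seeing the data were fits without MALAT1, NEAT1 and ribosomal RNA genes, without genes holding fractional counts, and with trends on GC content and length removed, as well as list counts with each library left out. Figures and text files were made with Python 3.11.15.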

Results

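Transcripts were measured in CAMA1 cells, an established human breast cancer line that expresses the estrogen receptor and carries an amplification of the fibroblast growth factor receptor gene FGFR1. The cells were kept without serum for 24 h and then given either PBS (vehicle) or the growth factor FGF2 at 5 ng/ml for 6 h. Each of these groups had 3 libraries of poly(A) RNA. The count totals ran from 21609117 to 23598392 in the vehicle group and from 22358660 to 23035030 in the FGF2 group. The groups lay apart on the first principal component of the log2 CPM, which held 86.5% of the variance. MALAT1 took 1.24% to 3.91% of the counts in the vehicle libraries and 2.0% to 3.85% in the FGF2 libraries, and ribosomal RNA genes took 0.304% to 1.63% and 0.515% to 1.02%. Levels are given as TMM-scaled CPM, mean ± SD with n = 3 libraries a group. Fold changes carry 95% intervals or standard errors from the edgeR fit, and positions are hg38 coordinates of the gene models in the deposited table. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, and those of lists from limma's camera with the same adjustment. The labels call the replicates biological without stating that they came from separate cultures or days, so p-values measure the spread between these samples, part of which may be technical.

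The comparison of FGF2 with vehicle asked which transcripts change when an FGF receptor ligand is added to serum-starved cells with amplified FGFR1. The intestinal mucin gene MUC2 (chromosome 11, 1074875 to 1110508) rose 222-fold (196 to 252), from 1.26 ± 0.172 to 282 ± 15.2 CPM. SPRY4, an inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142310427 to 142325055), rose 160-fold (122 to 211), from 0.142 ± 0.067 to 23.4 ± 1.81 CPM. The calpain protease gene CAPN8 rose 118-fold (97.6 to 142) and the metalloproteinase inhibitor gene TIMP1 rose 117-fold (99.9 to 137). On the other side, AKAP5, which encodes an anchoring protein of protein kinase A, fell from 24.3 ± 1.86 to 2.96 ± 0.615 CPM, 8.21-fold (6.90 to 9.78). CXXC4, an inhibitor of Wnt signalling, fell 6.79-fold (6.08 to 7.58) and F7, coagulation factor VII, fell 6.71-fold (5.94 to 7.58). Reads shared with other sequences leave some of these levels uncertain, since MUC2 had fractional counts in 3 libraries and F7 in 1, and exons of CXXC4 overlap LOC101929468 on the opposite strand by 96 bp.

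Of 14570 genes tested, 8807 changed by edgeR's test, of which 4371 rose and 4436 fell. The balance of directions depends on the scaling, with 3906 risen and 5014 fallen under upper quartile factors and 4440 and 4385 under DESeq2's size factors. Most changes were small. Of the changed genes, 5115 differed by less than 1.5-fold and 1832 by at least 2-fold, 1114 of them risen and 718 fallen. At 8-fold or more there were 212 risen genes and 16 fallen genes. In 97.0% of the changed genes all FGF2 libraries lay on one side of all vehicle libraries. Over all tested genes this held for 65.7%, where chance gives 10%. Among 12834 protein-coding genes tested, 4066 rose and 3915 fell. The 12 protein-coding genes with the largest rise, taken by the rule for named genes, also held the endothelial lipase gene LIPG (101-fold), METTL7B (90.7-fold), IGFL1 (68.1-fold), the ETS factor gene ETV4 (65.7-fold), the drug transporter gene ABCC3 (54.1-fold), the chemokine gene CXCL8 (51.1-fold), the cytokine gene LIF (50.9-fold) and B4GALNT3 (49.0-fold). Among the 12 with the largest fall were also ZCCHC24 (8.05-fold), FGD3 (6.5-fold), VWA2 (6.34-fold), PRR15L (5.65-fold), C2orf54 (5.63-fold), REEP1 (5.61-fold) and AHNAK2 (5.22-fold). The edgeR adjusted p of the 24 genes under that rule was at most 1.78e-09. The rule itself required each gene's FGF2 libraries to lie on one side of its vehicle libraries. VWA2 had fractional counts in 1 library, and METTL7B and FGD3 overlap exons of ITGA7 and LOC101927954 on the opposite strand, so their levels are uncertain as well.

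**Figure D1:**
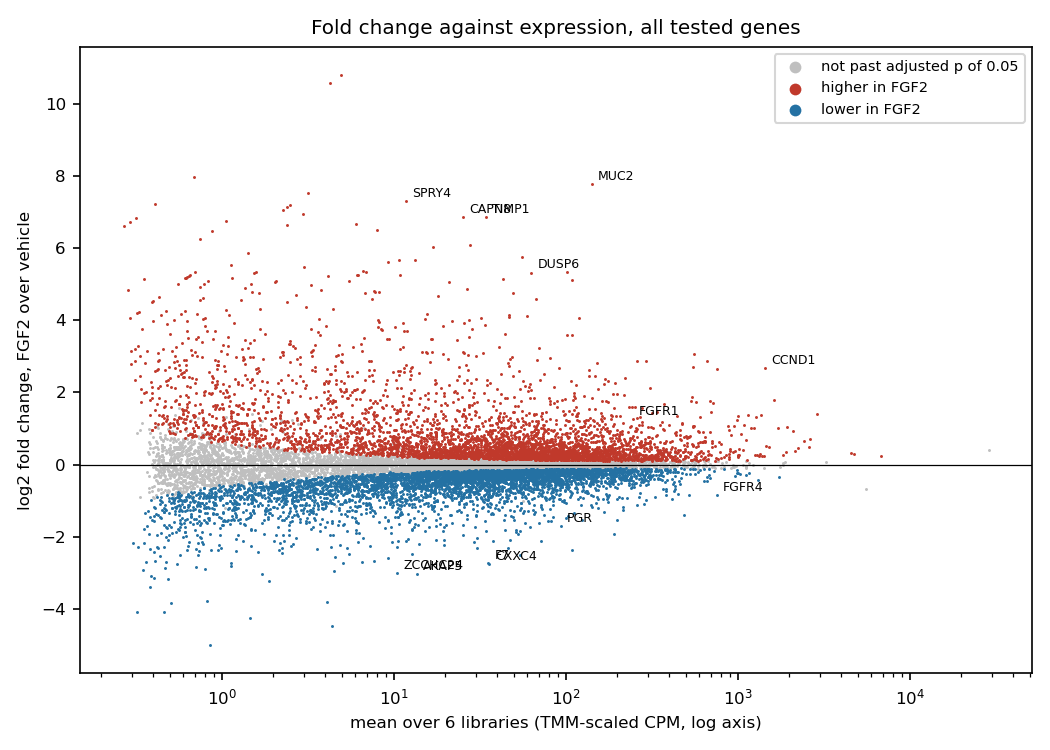
Log2 fold change of FGF2 over vehicle (vertical axis) against the mean of the 6 libraries in TMM-scaled CPM (horizontal log axis), with 1 point per tested gene, red for risen, blue for fallen and grey for not past an adjusted p of 0.05. Above a log2 fold change of 3, which is 8-fold, lie 212 red genes, with MUC2 at 7.80, and 16 blue genes lie as far below 0.

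FGFR1 itself (chromosome 8, 38411138 to 38468834) rose 2.40-fold (2.20 to 2.61), from 145 ± 12.8 to 346 ± 14.7 CPM, a log2 fold change of 1.26 ± 0.058 (SE) with an edgeR adjusted p of 2.61e-11. FGFR2 rose 2.50-fold (1.96 to 3.18) at low levels, from 1.82 ± 0.351 to 4.54 ± 0.373 CPM. FGFR4, the FGF receptor transcript with the highest level in vehicle, fell 1.79-fold (1.59 to 2.02), from 970 ± 123 to 541 ± 19.0 CPM. FGFR3 rose 1.45-fold (1.07 to 1.96), from 1.53 ± 0.154 to 2.22 ± 0.540 CPM, with an edgeR adjusted p of 0.0348. That call was lost without vehicle replicate 1 or 2 or FGF2 replicate 1 or 2 (adjusted p 0.0651, 0.0847, 0.212 and 0.0773), and with DESeq2 (0.153), limma voom (0.0573) and upper quartile factors (0.0525). Of the 28 tested FGF receptors and signalling adaptors, 10 rose, 12 fell and 6 did not pass the test, with the same numbers when adjusted over the list alone. GAB1, a docking protein downstream of the receptors, rose 1.93-fold (1.80 to 2.06) and the syndecan gene SDC4 rose 1.87-fold (1.75 to 2.0). The list's median log2 fold change was -0.06, its mean was 0.08, and camera put it on the higher side without a call (adjusted p = 0.938). FGFR1 had fractional counts in 3 libraries and FGFR2 and SDC4 in 2.

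FGFR1 lies in the 8p11-p12 region that is amplified together in breast cancers. Of 18 tested genes listed there, 8 rose, 3 fell and 7 did not pass the test, with the same counts adjusted over the list alone. After FGFR1 the largest rises were those of TACC1, from 153 ± 6.06 to 256 ± 8.29 CPM, and LETM2, from 14.3 ± 0.627 to 21.9 ± 2.21 CPM, while PLEKHA2 fell from 109 ± 9.18 to 66.4 ± 0.809 CPM. The list was not called by camera (median log2 fold change 0.10, adjusted p = 0.273). PLEKHA2 had fractional counts in 6 libraries and LETM2 in 3. Of the listed FGF family genes, not all of which encode receptor ligands, only 4 had enough counts for the test, too few for a test as a list. FGF13 rose 1.49-fold (1.32 to 1.69), from 12.3 ± 0.567 to 18.3 ± 1.30 CPM. FGF12 fell from 2.42 ± 0.730 to 1.29 ± 0.0998 CPM, FGF11 fell from 3.75 ± 0.586 to 2.79 ± 0.644 CPM (edgeR adjusted p = 0.0488), and the remaining one did not pass, with the same counts adjusted over the list alone. The FGF11 call was lost without vehicle replicate 1 or 3 or FGF2 replicate 1 (adjusted p 0.118, 0.173 and 0.259), and with DESeq2 (0.160), limma voom (0.0618), the fit without robust shrinkage (0.0576) and the genes with fractional counts left out (0.0521). The transcript of the FGF2 gene itself, with 3, 6 and 4 counts in vehicle and 3, 2 and 4 in treated libraries, was too low to be tested, and its exons overlap NUDT6 on the opposite strand by 1274 bp.

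Genes of the MAPK feedback and FGF synexpression group, which are transcribed in response to ERK signalling and in part restrain it, had the highest median of the lists tested. Of 18 tested, 14 rose and 4 fell, also when adjusted over the list alone, and each of the 14 rose at least 2-fold. The ERK phosphatase gene DUSP6 (chromosome 12, 89347825 to 89352859) rose 40.2-fold (35.8 to 45.2), from 3.06 ± 0.330 to 124 ± 4.76 CPM. ETV4, an ETS transcription factor gene, rose from 0.502 ± 0.163 to 33.6 ± 1.84 CPM and its relative ETV5 rose 9.50-fold (6.46 to 14), from 0.269 ± 0.057 to 2.58 ± 0.312 CPM. PHLDA1, with fractional counts in 2 libraries, rose 33.4-fold (28 to 39.9). The list's median log2 fold change was 2.74 (camera adjusted p = 7.54e-34), and it was the only list still called with an estimated correlation (adjusted p = 0.00579). SPRY2 was not tested, with 2 counts in each vehicle library and 11, 9 and 13 in the FGF2 libraries.

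**Figure D2:**
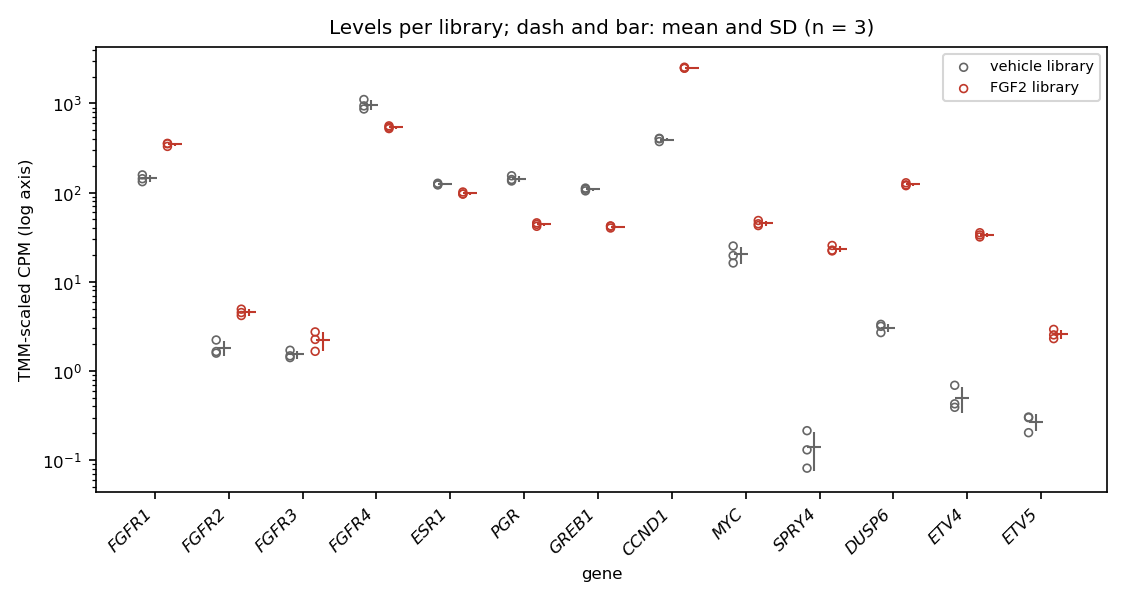
TMM-scaled CPM (vertical log axis) of the FGF receptor genes, estrogen receptor genes, CCND1, MYC and MAPK feedback genes (horizontal axis), with an open circle per library, grey for vehicle and red for FGF2, and a dash and bar for the mean and SD of 3 libraries. FGFR1 goes from 145 to 346 CPM, FGFR4 from 970 to 541 CPM, PGR from 143 to 43.9 CPM and DUSP6 from 3.06 to 124 CPM.

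The immediate and delayed early genes, transcription factors and signalling proteins induced within minutes to hours of growth factor addition, were also higher. Of 34 tested, 27 rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone. LIF rose from 0.502 ± 0.173 to 26.0 ± 3.44 CPM. The zinc finger factor genes EGR2 and EGR3 rose 38.4-fold (17.5 to 84.6) and 28.4-fold (15.6 to 51.7), and FOSL1, an AP-1 subunit gene, had 2 counts in all vehicle libraries together, with a ratio of 48.7 (95% counting interval 13.1 to 409). MYC rose 2.22-fold (1.78 to 2.78), from 20.3 ± 4.50 to 45.3 ± 3.03 CPM. The list's median log2 fold change was 1.30 (camera adjusted p = 2.36e-12, but adjusted p = 0.192 with an estimated correlation). Vehicle replicate 3 held higher levels of several of these genes than the other vehicle libraries. EGR1 stood at 70.3, 71.5 and 335 CPM in the vehicle libraries against a mean of 1172 CPM after FGF2, and FOS at 16.1, 16.1 and 70.3 CPM against 44.3 CPM. FOS, FOSB and NR4A1 did not pass the test with all libraries (edgeR adjusted p 0.701, 0.476 and 0.527) and did without vehicle replicate 3 (0.00438, 0.000701 and 0.00231), with folds of 2.77, 4.67 and 3.94. Without that library 30 genes of the list rose and 1 fell, against 24 risen with any 1 of the other libraries left out. Without vehicle replicate 3 the log2 fold changes of EGR1, EGR2 and EGR3 went from 2.88, 5.26 and 4.83 to 4.05, 7.43 and 6.23, while the number of fallen genes was also 1 without vehicle replicate 1 or FGF2 replicate 2. EGR1, FOS, FOSB and NR4A1 fall outside the rule for named genes and were chosen after their values were seen. NR4A1 had fractional counts in 2 libraries and FOSL1 in 1.

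**Figure D3:**
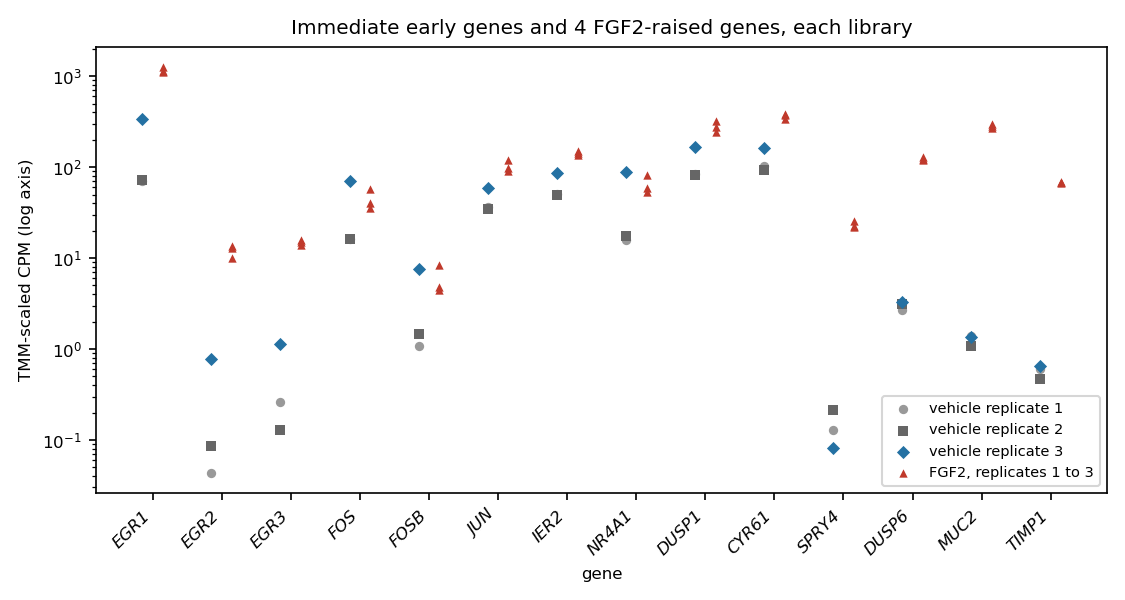
TMM-scaled CPM (vertical log axis) of 10 immediate early genes and of SPRY4, DUSP6, MUC2 and TIMP1 (horizontal axis) in each library, with circles, squares and blue diamonds for vehicle replicates 1, 2 and 3 and red triangles for the FGF2 libraries. EGR1 lies at 335 CPM in vehicle replicate 3 and at 70.3 and 71.5 CPM in the other vehicle libraries, while SPRY4 and MUC2 in vehicle replicate 3 stay at 0.0811 and 1.34 CPM.

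Among estrogen receptor genes the receptor ESR1 fell 1.27-fold (1.18 to 1.36), from 124 ± 2.77 to 98.1 ± 2.95 CPM (edgeR adjusted p = 5.65e-06). PGR, the progesterone receptor gene and a classical estrogen target (chromosome 11, 101029624 to 101129813), fell 3.26-fold (2.99 to 3.56), from 143 ± 10.1 to 43.9 ± 1.96 CPM. GREB1, a cofactor and target of the receptor, fell 2.62-fold (2.43 to 2.83), from 109 ± 3.92 to 41.4 ± 1.19 CPM. CCND1, which encodes cyclin D1 (chromosome 11, 69641105 to 69654474), rose 6.37-fold (5.90 to 6.88), from 394 ± 17.7 to 2508 ± 35.2 CPM. Of the 36 tested estrogen receptor targets, 17 rose, 9 fell and 10 did not pass, also when adjusted over the list alone, and camera did not call the list (median log2 fold change 0.09, adjusted p = 0.319). CCND1 and EGR3, which rose here, are also on the MAPK feedback list and on the early gene list. TFF1, MYB, RARA, STC2 and OLFM1, which are on neither of those lists, also rose at least 2-fold. They fall outside the rule for named genes. GREB1 had fractional counts in 6 libraries, and exons of PGR overlap LOC101054525 on the opposite strand by 1037 bp. Over the libraries PGR held 95.9 CPM and LOC101054525 0.411 CPM on average, without TMM scaling.

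Luminal lineage genes, which mark the secretory epithelium of the breast, divided. Of 23 tested, 11 rose, 6 fell and 6 did not pass, with the same counts adjusted over the list alone. AGR2, a disulfide isomerase of secretory cells, rose 7.26-fold (6.76 to 7.81), from 62.8 ± 3.05 to 456 ± 10.5 CPM, the keratin genes KRT18 and KRT8 rose 3.44-fold (3.13 to 3.77) and 2.64-fold (2.41 to 2.90), and ELF5 fell from 2.05 ± 0.440 to 0.709 ± 0.0371 CPM. The median log2 fold change was 0.14 (camera adjusted p = 0.000891, adjusted p = 0.0830 with an estimated correlation). With the genes holding fractional counts left out, an alternative chosen after seeing the data, the call was lost (adjusted p = 0.110). KRT8 and KRT18 had fractional counts in 6 and 5 libraries and their exons overlap on opposite strands by 270 bp, so their levels are uncertain. Of 17 tested basal and mesenchymal markers, 12 rose, 2 fell and 3 did not pass, also when adjusted over the list alone. The risen markers stayed low, with means of at most 7.99 CPM after FGF2. CDH3 and TWIST1 were the genes that fell, and VIM did not pass. These 3 genes fall outside the rule for named genes. The stricter filter on low counts left too few markers for a test of the list. The collagenase gene MMP13 rose from 0.0562 ± 0.0655 to 0.999 ± 0.216 CPM, a log2 fold change of 4.03, or 5.25 without vehicle replicate 2. The N-cadherin gene CDH2 rose from 0.114 ± 0.0917 to 3.96 ± 0.521 CPM, a log2 fold change of 5.07, or 5.88 without vehicle replicate 1. The list's median log2 fold change was 1.49 (camera adjusted p = 0.0110, adjusted p = 0.0830 with an estimated correlation, and 0.0561 with trends on GC content and length removed). The number of fallen markers was 1 without vehicle replicate 2 or 3 or FGF2 replicate 1 or 3.

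Growth and division genes went in different directions. Of 37 tested genes of ribosome biogenesis and MYC targets, 33 rose, 0 fell and 4 did not pass by edgeR, and 1 fell when adjusted over the list alone, at an unadjusted p under 0.05 or without vehicle replicate 2. DESeq2 and limma voom also gave 33 risen and 0 fallen. ODC1, the first enzyme of polyamine synthesis, rose 2.80-fold (2.60 to 3.0), from 55.0 ± 1.73 to 154 ± 3.64 CPM, RRP12 rose 2.24-fold (2.02 to 2.49) and UTP20, a processome subunit gene, rose 1.84-fold (1.71 to 1.99). Their median log2 fold change was 0.49 (camera adjusted p = 1.33e-06, adjusted p = 0.0830 with an estimated correlation). Of 32 G2/M phase genes, 26 fell, 0 rose and 6 did not pass by edgeR, with 1 risen when adjusted over the list alone, at an unadjusted p under 0.05 or without vehicle replicate 3. DESeq2 gave 23 fallen and limma voom 25, with 0 risen by either. Each fall was under 2-fold. TOP2A, topoisomerase II of dividing cells, fell from 88.6 ± 2.12 to 51.6 ± 2.01 CPM, the mitotic kinesin gene KIF23 from 37.6 ± 1.38 to 21.6 ± 1.61 CPM and the mitotic kinase gene AURKB from 2.19 ± 0.123 to 1.22 ± 0.260 CPM. Over this list the median log2 fold change was -0.42 (camera adjusted p = 0.00121, adjusted p = 0.0830 with an estimated correlation). Of 33 G1/S and S phase genes, 11 rose, 7 fell and 15 did not pass, also when adjusted over the list alone. MCM6, a subunit of the replicative helicase, rose 2.29-fold (2.11 to 2.49) and E2F2 and CCNE1, a cell cycle transcription factor gene and the cyclin E1 gene, fell from 7.82 ± 0.944 to 2.51 ± 0.264 CPM and from 9.53 ± 0.835 to 4.45 ± 0.229 CPM. That list was not called (camera adjusted p = 0.977). Its median log2 fold change was 0.03, or -0.02 with upper quartile factors, and camera put it on the lower side. E2F2 had fractional counts in 1 library and overlaps LOC101928163 on the opposite strand by 56 bp.

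Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and so enter these libraries in part, gave 14 fallen, 2 risen and 7 not past the test of 23, with the same counts adjusted over the list alone. HIST1H4D fell from 2.84 ± 0.757 to 1.08 ± 0.0389 CPM and HIST1H4E from 1.95 ± 0.102 to 1.0 ± 0.179 CPM. The list had a median log2 fold change of -0.59 and was not called (camera adjusted p = 0.0520). It was called with limma voom (adjusted p 0.0112), no filter on low counts (0.0149), the replicate number as a block (0.0154) and fry (0.000949), and without vehicle replicate 1 (0.0326) or FGF2 replicate 2 (0.0378). Under the other alternatives it was not, with an adjusted p of 0.0507 to 0.385. Of 27 FOXO targets and quiescence genes, 13 fell, 5 rose and 9 did not pass, also when adjusted over the list alone. TP53INP1, a stress-induced regulator of autophagy, fell 3.78-fold (3.53 to 4.06), from 300.5 ± 13.5 to 79.4 ± 1.79 CPM, TXNIP, an inhibitor of glucose uptake, fell 2.64-fold (2.47 to 2.82) and BCL2L11, which encodes the pro-apoptotic protein BIM, fell 2.65-fold (2.42 to 2.91). The members had a median log2 fold change of -0.15 (camera adjusted p = 0.00179, adjusted p = 0.0830 with an estimated correlation). Of 22 apoptosis regulators, 10 rose, 8 fell and 4 did not pass, also when adjusted over the list alone. CDKN1A, the p21 cell cycle inhibitor gene, rose 12.2-fold (11 to 13.4), from 16.6 ± 1.37 to 202 ± 12.9 CPM, BIRC3 rose 5.68-fold (4.52 to 7.13) and BCL2A1 was at least 12.8-fold higher, against a floor of 3 counts over the vehicle group, which had 0. The list was not called (camera adjusted p = 0.273), and its median log2 fold change of 0.02, with BCL2A1 at its fitted value or at its bound, was -0.02 with upper quartile factors.

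Sterol and fatty acid synthesis genes were mostly higher. Of 29 tested, 21 rose, 4 fell and 4 did not pass, with 5 fallen when adjusted over the list alone. HMGCS1, an early enzyme of cholesterol synthesis, rose 3.67-fold (3.43 to 3.94), from 233 ± 2.41 to 856 ± 39.7 CPM, and ELOVL6, a fatty acid elongase gene, rose 5.48-fold (4.08 to 7.37), with fractional counts in 2 libraries and in 1. The median log2 fold change was 0.62 (camera adjusted p = 1.12e-10, adjusted p = 0.0830 with an estimated correlation). Of 22 endoplasmic reticulum chaperones, 20 rose, 0 fell and 2 did not pass by edgeR, also when adjusted over the list alone, and 1 fell without vehicle replicate 3. At an unadjusted p under 0.05 and by DESeq2 and limma voom 0 fell as well. HSPA5, the luminal HSP70, rose 2.36-fold (2.20 to 2.53), HSP90B1 rose from 567 ± 17.7 to 1194 ± 27.2 CPM and DNAJB9 rose from 40.8 ± 2.79 to 104 ± 4.52 CPM. Their median log2 fold change was 0.63 (camera adjusted p = 3.71e-08, adjusted p = 0.0830 with an estimated correlation). HSPA5 had fractional counts in 5 libraries and HSP90B1 in 2, HSP90B1 holds MIR3652 on its own strand, and DNAJB9 overlaps THAP5 on the opposite strand. Of 29 genes of the ATF4 amino acid response, 18 rose, 6 fell and 5 did not pass, also when adjusted over the list alone. SLC7A11, the cystine transporter gene, rose 11.7-fold (10.3 to 13.3), from 4.30 ± 0.351 to 50.3 ± 2.53 CPM, CHAC1 rose 4.97-fold (4.0 to 6.17) and VLDLR, a lipoprotein receptor gene, fell from 3.59 ± 0.332 to 0.786 ± 0.0889 CPM. Over this list the median log2 fold change was 0.30 (camera adjusted p = 0.000541, adjusted p = 0.0830 with an estimated correlation). SLC7A11 had fractional counts in 1 library, and SLC7A11 and VLDLR overlap the antisense genes SLC7A11-AS1 and VLDLR-AS1 by 276 bp and 344 bp.

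Glycolysis and hypoxia response genes gave 14 risen, 7 fallen and 6 not past the test of 27, also when adjusted over the list alone. CA9, a hypoxia-inducible carbonic anhydrase gene, had 1 count over the vehicle group, with a ratio of 150.1 (95% counting interval 26.5 to 5970), EGLN3, an oxygen-sensing prolyl hydroxylase gene, rose 6.00-fold (5.48 to 6.58) and PFKP, a phosphofructokinase gene, rose from 28.7 ± 3.41 to 103 ± 9.13 CPM. The fitted log2 fold change of CA9, which depends on the prior count, was 6.76, or 8.58 without vehicle replicate 2, which held its 1 vehicle count, and 6.12 with limma voom. The list was not called (median log2 fold change 0.13, camera adjusted p = 0.236). Of 18 cytosolic heat shock genes, 8 rose, 2 fell and 8 did not pass, also when adjusted over the list alone, with no call for the list (median log2 fold change 0.10, camera adjusted p = 0.273). The constitutive chaperone gene HSPA8 rose 2.02-fold (1.88 to 2.17) and the small heat shock gene HSPB1 fell from 349 ± 68.8 to 236 ± 23.2 CPM with an edgeR adjusted p of 0.0425. The HSPB1 call was lost without vehicle replicate 2 and without FGF2 replicate 1, 2 or 3 (adjusted p 0.105, 0.0533, 0.124 and 0.106) and with no filter on low counts (0.0748), and with any of these FGF2 libraries left out 1 gene of the list fell. HSPA8 had fractional counts in 4 libraries and HSPB1 in 5. Of 46 cytosolic ribosomal protein genes, 8 rose, 3 fell and 35 did not pass, against 5 risen and 1 fallen when adjusted over the list alone. Without vehicle replicate 2, 9 fell. With any of the FGF2 libraries left out 5 rose, and without FGF2 replicate 1 or 2 1 fell. RPL10A went from 454 ± 25.8 to 530.3 ± 13.4 CPM, a rise of 1.17-fold (1.09 to 1.25), with fractional counts in 5 libraries. The list was not called (camera adjusted p = 0.986), and its median log2 fold change was 0.03, or -0.02 with upper quartile factors.

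Cytokine and NF-kB target genes were higher after FGF2. Of 18 tested, 15 rose, 1 fell and 2 did not pass, also when adjusted over the list alone, with 2 fallen without vehicle replicate 3. The chemokine gene CXCL8 (chromosome 4, 73740506 to 73743716) rose from 0.408 ± 0.0184 to 21.1 ± 1.80 CPM, ICAM1, an adhesion receptor for leukocytes, rose 9.61-fold (8.57 to 10.8), from 7.70 ± 0.505 to 74.1 ± 5.15 CPM, and CCL20 had 2 counts over the vehicle group, with a ratio of 169.8 (95% counting interval 46.6 to 1408). The members had a median log2 fold change of 1.86 (camera adjusted p = 3.52e-18, adjusted p = 0.0830 with an estimated correlation). Of 26 interferon response genes, 10 rose, 3 fell and 13 did not pass, also when adjusted over the list alone, and 5 rose without FGF2 replicate 3. The exonuclease gene ISG20 rose 5.87-fold (5.07 to 6.78) and the antiviral GTPase gene MX1 rose 1.89-fold (1.55 to 2.31), from 4.36 ± 0.298 to 8.26 ± 1.49 CPM, with fractional counts in 1 and in 2 libraries. The list was not called (median log2 fold change 0.23, camera adjusted p = 0.273).

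YAP/TEAD and TGF-beta targets gave 15 risen, 5 fallen and 2 not past the test of 22, also when adjusted over the list alone. CRIM1, a membrane-bound modulator of BMP signalling, rose 11.2-fold (9.80 to 12.9), from 2.74 ± 0.155 to 30.9 ± 0.927 CPM, and ID1, an inhibitor of DNA-binding factors, rose 7.30-fold (5.99 to 8.89). CTGF rose with a log2 fold change of 2.29, or 3.24 without vehicle replicate 3. The median log2 fold change was 0.52 (camera adjusted p = 4.30e-05, adjusted p = 0.0830 with an estimated correlation). Of 17 receptor tyrosine kinases and EGF family ligands, 10 rose, 2 fell and 5 did not pass, also when adjusted over the list alone. MET, the hepatocyte growth factor receptor gene, rose 13-fold (7.62 to 22.1), from 0.126 ± 0.0852 to 1.71 ± 0.233 CPM. The EGF receptor ligand genes AREG and HBEGF rose 8.34-fold (7.07 to 9.85) and 6.40-fold (5.51 to 7.43), from 4.15 ± 0.363 to 34.6 ± 4.59 CPM and from 3.42 ± 0.296 to 21.9 ± 1.51 CPM. Their median log2 fold change was 0.69 (camera adjusted p = 3.09e-05, adjusted p = 0.0830 with an estimated correlation). AREG and HBEGF are on the early gene list too.

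Markers of other cell types were few. Of 5 tested fibroblast markers, 3 rose, 1 fell and 1 did not pass, also when adjusted over the list alone. COL5A1, a collagen chain gene, rose from 184 ± 10.3 to 248 ± 6.80 CPM, S100A4 rose from 48.4 ± 5.54 to 61.9 ± 3.75 CPM and ACTA2, smooth muscle actin, fell from 15.8 ± 2.11 to 6.29 ± 0.679 CPM. Their exons overlap LOC101448202 (188 bp), LOC101928034 (108 bp) and ACTA2-AS1 (1032 bp) on the opposite strand, and ACTA2 had fractional counts in 1 library. The list was not called (camera adjusted p = 0.938), with a median log2 fold change of 0.30 and a mean of -0.03. Of the leukocyte and endothelial markers only the integrin gene ITGAM was tested, and it rose from 0.382 ± 0.123 to 0.848 ± 0.127 CPM (edgeR adjusted p = 0.00509, with DESeq2 0.0661). Without vehicle replicate 1, 2 or 3 or FGF2 replicate 1, 2 markers of that list were tested and both rose. No mitochondrially encoded gene was in the deposited table. In all, camera called 13 of the 24 lists tested, 11 higher and 2 lower.

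**Figure D4:**
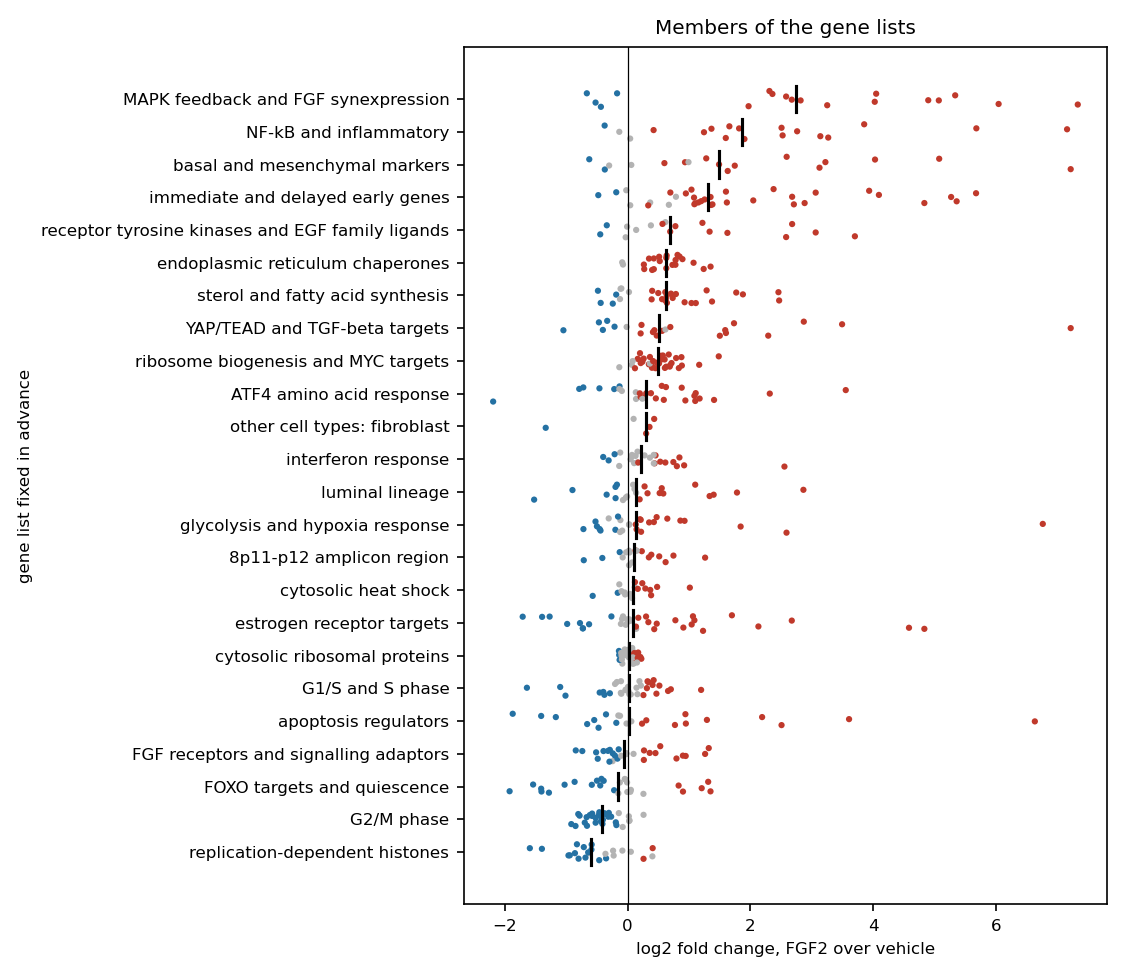
Log2 fold change of FGF2 over vehicle (horizontal axis) of the members of the 24 tested gene lists (vertical axis), with 1 point per gene, red for risen, blue for fallen and grey for not past an adjusted p of 0.05, and a black line at each list's median. The medians run from -0.59 for the replication-dependent histones and -0.42 for the G2/M genes to 1.86 for NF-kB targets and 2.74 for the MAPK feedback genes.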

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

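The fits without abundant RNAs, without genes holding fractional counts and with GC and length trends removed were chosen after seeing the data, and the others before. Of the 8807 changed genes none was called in the opposite direction under any alternative. Other scalings, filters, DESeq2, limma voom and the fit without robust shrinkage gave 7046 to 9465 changed genes, and leaving out 1 library at a time gave 7892 to 9106. A test against a fold of 1.5 called 2319 genes (1375 risen, 944 fallen), which asks for a larger change. Leaving out the genes with fractional counts gave 5738 of 9566 tested, since fewer genes were tested. Upper quartile factors moved the median log2 fold change of all genes from -0.01 to -0.05 and gave 3906 risen and 5014 fallen genes, against 4371 and 4436. Of the 24 lists, 13 were called, against 12 to 14 under the other scalings, filters, limma voom, the fit without robust shrinkage and the added fits, and 13 to 14 with 1 library left out. The stricter filter called 12 of 23 lists, with the basal and mesenchymal list no longer tested. An estimated correlation left 1 call, the MAPK feedback list. The luminal, basal and FOXO lists lost their calls at estimates of -0.016, -0.040 and -0.014, under the preset of 0.01. These values argue against a correlation above the preset as the cause for those lists. The MAPK feedback list had an estimate of 0.00995, also under the preset. Its camera adjusted p still went from 7.54e-34 to 0.00579. The version with an estimate thus gave far larger p-values without a higher correlation, so a lost call alone is no evidence of correlated genes. The other lost lists had estimates above the preset, up to 0.536 for the NF-kB list. How much of their loss came from correlation was not tested. Fry, which sets no list against other genes, called 21 (18 higher, 3 lower). With the replicate number as a replicate block, 9158 genes and 14 lists were called. Deviations of libraries with the same number correlated over genes at -0.149, 0.236 and -0.132, and not every library correlated best with its own number, so the numbers were not taken as pairs. HSPB1 was not past the threshold in that fit (adjusted p = 0.126). Of the 124 named genes tested, 117 kept direction and side of the threshold with DESeq2, at least 119 with any 1 library left out and 124 with DESeq2's size factors in edgeR. Calls of low or slightly changed genes (ADM, OAS2, RSAD2, FGF11, FGFR3, COL1A1, ITGAM, HSPB1, RPL35) were lost under at least 1 alternative and the cause was not tested. The simulated comparison, in which far fewer genes changed than here, recovered 50% of genes at 1.2-fold, so smaller changes can have been missed at this depth.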

Other observations

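The tests of vehicle replicate 3, of copies of the amplified region and of fewer cells after G1, the gene families below and the genes named from them were chosen only after the result was seen. Grouping genes by the root of their symbol gave 170 families with at least 10 tested members, of which camera called 5 (0 with an estimated correlation). Receptors of the tumor necrosis factor family were mostly higher after FGF2. Of 10 tested, 9 rose and 1 fell, with a median log2 fold change of 1.64 (camera adjusted p = 1.07e-05, adjusted p = 0.833 with an estimated correlation). TNFRSF12A, the receptor of the cytokine TWEAK, rose 5.50-fold, from 45.4 ± 2.33 to 249.7 ± 2.95 CPM, and the death receptor gene TNFRSF21 rose 3.96-fold, from 11.8 ± 0.363 to 46.6 ± 4.03 CPM. TNFRSF25 was the member that fell, from 20.1 ± 3.15 to 11.2 ± 1.19 CPM, but its exons overlap PLEKHG5 on the same strand by 4992 bp. TNFRSF12A and TNFRSF21 had fractional counts in 1 library each. Of 16 keratins, 14 rose and 1 fell, with a median log2 fold change of 1.38 (camera adjusted p = 1.07e-05, adjusted p = 0.980 with an estimated correlation). KRT15 and KRT16, keratins of stratified epithelia, rose from 2.27 ± 0.504 to 9.20 ± 0.234 CPM and from 1.86 ± 0.176 to 7.92 ± 1.11 CPM, and KRT24 fell from 3.76 ± 0.202 to 1.25 ± 0.133 CPM. The hair keratin genes KRT81 and KRT86 also rose, 5.60-fold and 7.38-fold, but are close paralogs and held fractional counts in 4 and 5 libraries, as did KRT16 in 5, and KRT15 overlaps MIR6510 on its own strand by 2 bp.

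Other genes with high levels and large changes, also picked after their values were seen, were the lysosomal protease gene CTSV (4.86 ± 0.295 to 197.5 ± 4.54 CPM), the cornified envelope gene CDSN (6.06 ± 1.03 to 211.8 ± 10.6 CPM), CYP1B1, a xenobiotic-metabolizing enzyme gene (3.48 ± 0.624 to 94.7 ± 4.88 CPM) and the chemokine gene CCL22 (5.29 ± 0.417 to 128.7 ± 17 CPM), all higher by edgeR's test. NR1D2, a circadian repressor gene, fell 4.24-fold (3.83 to 4.69), from 76.9 ± 3.24 to 18.1 ± 1.44 CPM, and BMF, a pro-apoptotic gene of the BIM class, fell 3.65-fold (3.31 to 4.03), from 81.0 ± 4.77 to 22.2 ± 1.52 CPM. CDSN has models on 6 chromosomes or contigs, so its reads may be divided, and CCL22 held fractional counts in 3 libraries. With the genes holding fractional counts left out, 5738 genes changed.

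Across splits of the 6 libraries into groups of 3, 1 of 10 gave as many changed genes as the real one, which is the real one itself (8807). The highest of the others was 0 by edgeR, with up to 151 genes at an unadjusted p under 0.05. For lists, 3 of 10 splits gave as many calls, the real one included, with 13 in the real split and 14 in the highest other. With 10 splits the share cannot go under 0.1, which is too few for a decision on chance. Every other split also puts both treatments in each group, in unequal numbers. Part of the FGF2 effect then stays between the groups and part adds to the spread within them. Neither the 0 genes nor the list calls of these splits thus show what chance alone gives.

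Vehicle replicate 3 held 10 immediate early genes, EGR1, EGR2, EGR3, FOS, FOSB, JUN, IER2, NR4A1, DUSP1 and CYR61, at least 1.5 times above both other vehicle libraries. IER2 and NR4A1 had fractional counts in 2 libraries. RNA or cells from FGF2-treated cultures would bring the strongest FGF2-raised transcripts too. The 12 most risen genes reached a median of 0.181% of their FGF2 rise in that library, against 36.7% for the 10 early genes. Both sets were picked from these data. The 12 have large rises over a vehicle mean that includes this library, and the 10 were taken for high levels in it. The contrast between the sets was thus partly fixed by their choice. A mixture would still raise each of the 12 genes by its share, so their values argue against one large enough for the early genes. The library had the highest ribosomal RNA share (1.63%), but vehicle replicate 2, at 1.24%, held these genes at a median of 0.989 times vehicle replicate 1, which argues against ribosomal RNA content. A brief stimulus to that culture before lysis, such as handling, is a candidate explanation that stays open, and it may hide rises of FOS, FOSB and NR4A1 after FGF2.

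FGFR1 rose in a line known to carry an amplification of the gene, whose copy number was not measured here. If the FGF2 cultures held more copies of the region, other genes amplified with FGFR1 would rise alike. The other 17 tested genes of the 8p11-p12 list had a median log2 fold change of 0.0736 (order-statistic limits -0.02 to 0.35, SD of the members 0.359) against 1.26 for FGFR1. Among them TACC1, LETM2 and PLEKHA2 had log2 fold changes of 0.75, 0.62 and -0.71. This argues against more copies of the whole listed region. It cannot decide on a shorter stretch, since which genes are amplified together in this line is not known. Over 3 other scalings the log2 fold change of FGFR1 was 1.22 to 1.27, which argues against the choice among them as the cause. Each of them takes the bulk of the genes as unchanged, so a change in total RNA per cell would not show. All 3 FGF2 libraries stood above vehicle after 6 h of treatment, at 357, 330 and 353 CPM against 158, 133 and 143 CPM. If the replicates were separate cultures, so even a rise argues against copies gained by chance in single cultures during treatment. Copies were not measured, so a rise of the FGFR1 transcript after its ligand without more copies stays a hypothesis. Fractional counts of FGFR1 in 3 libraries, and whether transcription or stability changed, stay open.

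G2/M genes fell while CCND1, MYC and ribosome biogenesis genes rose. The cell cycle inhibitor gene CDKN1A rose as well, 12.2-fold, and CCNE1 and E2F2 fell. With trends on GC content and length removed the G2/M median log2 fold change was -0.415 (upper limit -0.30). This argues against those trends as the whole cause. Over 3 other scalings the median was -0.468 to -0.418, which argues against the choice among them as the whole cause. All of these scalings take the bulk of the genes as unchanged, so a change in total RNA per cell would not show. A smaller share of cells in all phases after G1 would lower G1/S and S phase genes as well. These had a median of 0.0271 (limits -0.11 to 0.26), but 11 rose and 7 fell, with an SD of the members of 0.539, so the median decides nothing. The histones made in S phase had a median of -0.59 (limits -0.80 to -0.24), the direction that fewer cells in S phase would give. That list was not called (camera adjusted p = 0.0520), and its transcripts enter poly(A) libraries only in part, so it decides nothing either. Fewer cells in all phases after G1, fewer cells in G2 and mitosis alone, or lower levels of these transcripts per cell may each give this pattern and stay open, since cell cycle position was not measured.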
